A study of Mus musculus with 16 samples.

How the data were processed

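Liver RNA from 16 mice was sequenced in a design of genotype by infection. The mice were of mixed strain background, wildtype or knockout for Mkp-1 (the protein of the gene Dusp1, a phosphatase that switches off mitogen-activated protein kinases), and were injected intravenously with E. coli or with buffer (PBS). Livers were taken 24 h after injection, per the labels' protocols. Each of the 4 groups held 4 mice, and each mouse is a replicate. Ribosomal RNA was depleted and directional libraries were made from total RNA, per the labels' protocols.

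The deposited values are whole-number counts of reads per gene symbol, 1 table for each of 2 sequencing runs of every library, 32 tables in all. Per the submitters' processing notes, reads were handled with Trim Galore 0.4.0, TopHat2 2.1.0 and HTSeq 0.6.0 on the mouse build mm10, so the authors' counts were not normalized. The annotation version, the strand setting of the counter and its other options are not given in the sources used here. Reads of near-identical genes (the Saa, Mup, H2, Reg, Gbp, Acot, Acsm and Cyp2 families and copies of Rps2) could be split or lost by such counting, and their values are uncertain, as are those of genes that overlap. Counts that name no gene were left out of library sizes and tests. Reads outside annotated genes took 40.4 to 47.8% of uniquely placed reads per mouse, and reads shared between genes 0.151 to 0.203%.

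The 2 runs of a library were summed, giving 16443056 to 24989997 gene counts per mouse. Between runs of 1 library the chi-square per degree of freedom was 1.16 to 1.28 over genes with at least 20 counts, near sampling noise. Levels are given as CPM, counts scaled to the effective library size, means ± SD of 4 mice. Intervals and floors drawn from counts cover counting error only. Of 24062 gene symbols, 23885 matched a gene of the reference annotation of the same mouse build, and 177 did not; coordinates are 1-based on that build.

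Differences were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with TMM factors, on genes kept by filterByExpr (13678 genes). All 16 mice entered 1 fit with a mean per group and a shared estimate of spread, and p was adjusted by Benjamini-Hochberg over the genes tested. A gene was called past the threshold at an adjusted p under 0.05. Adjusted p without another name is this test's. The 5 comparisons were infection in wildtype mice, infection in mice labelled knockout, genotype in uninfected mice, genotype in infected mice, and the interaction, which tests the difference of the infection effects. Dusp1 was also compared by exact two-sided permutation of log2(CPM + 0.5), over all 70 assignments of 8 mice. Genes within 10 Mb of Dusp1 were compared with all others by Fisher's exact test, two-sided.

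The pathway and marker lists were written before the data were examined, as were the design, the main tests and the planned settings. A list of genes that fall in liver after birth was written later, after other genes of the uninfected mice had been seen. There were 24 pathway lists and 12 lists of cell type markers. The pathway lists cover NF-kB and Toll-like receptor signalling, interferon-induced genes, the acute phase, the negative acute phase, cytokines and chemokines, genes induced by mitogen-activated protein kinases, p53 and cell death, oxidative stress and metal response, endoplasmic reticulum stress, glucocorticoid targets, cell cycle, circadian genes, growth hormone and IGF1, complement, coagulation, amino acid and urea metabolism, glucose metabolism, oxidative phosphorylation, fatty acid oxidation, lipogenesis, lipid storage and transport, cholesterol synthesis, bile acids, and xenobiotic metabolism. The marker lists cover hepatocytes, neutrophils, Kupffer cells, monocytes, T and NK cells, B cells, sinusoidal endothelium, stellate cells, cholangiocytes, erythroid cells, pancreas and adipose tissue. Lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjusted p of lists is over the lists of a kind within a comparison. Camera compares a list with all other genes, so a list can be past the threshold with few members past it.

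Genes were named by a rule fixed beforehand: Dusp1; the 6 largest rises and 6 largest falls per comparison among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between groups (not asked of the interaction), without predicted genes, clone symbols and small RNAs; and members of lists past the threshold with the smallest p. The last part was narrowed after values had been seen, to 2 members in a list's main direction and 1 in the other, from the 8 pathway and 4 marker lists with the smallest p; the counts of a list cover all its measured members. The values of 1 gene named by this rule are not reported here.

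The tests were tried on simulated counts drawn from the means and library sizes of these mice. Of genes changed by 1.5, 2 and 4 times, 49.3, 64.2 and 97% were recovered for infection in wildtype mice, 41.8, 67.2 and 90.9% for infection in mice labelled knockout, 31.3, 67.2 and 93.9% for genotype in uninfected mice, 34.3, 64.2 and 92.4% for genotype in infected mice, and 11.9, 55.2 and 77.3% for the interaction. The bound that this simulation had to meet for 4-fold changes was lowered after the interaction's value was seen. False calls numbered 11, 5, 10, 8 and 9 of 13453 unchanged genes in that order, and 0 unchanged lists were called. Genes were drawn independently of one another and few were changed. The simulation therefore does not show how camera fares with correlated genes, or TMM with many changed ones.

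The alternatives were RLE factors, library totals, TMM without the 50 most abundant genes, DESeq2 1.42.0, limma voom with quality weights, other count filters, each run alone, only the mice compared, the mouse number as a block, an adjusted p under 0.01, and leaving out each mouse. Added after seeing the data were removal of trends with GC content, totals without the 50 most abundant genes, and leaving out each mouse in the tests of position and of the relation between infection effects. A covariate for sex was planned for mice of both sexes and was not fitted, since all 16 libraries had the male pattern. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.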

Results

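RNA-seq counts were obtained from the livers of 16 mice: 4 wildtype and 4 Mkp-1 knockout mice given buffer, and 4 wildtype and 4 knockout mice 24 h after intravenous E. coli. The design asks how systemic infection changes the liver transcriptome and how the loss of Mkp-1 alters it. Gene counts per mouse averaged 22072941 ± 2011354 in uninfected wildtype, 20189098 ± 1985975 in uninfected knockout, 21044358 ± 1692447 in infected wildtype and 18585543 ± 1542658 in infected knockout mice (SD, n = 4 each). In 0 of the 16 libraries did Xist, the transcript of the silenced X chromosome, exceed the Y-linked gene Ddx3y. The first principal component held 65.1% of the variance and parted infected from uninfected mice, and the second held 21.9% and parted the genotypes among infected mice. Among uninfected knockout mice, mouse 3 lay at −93.6 on the first component, within the wildtype range of −97.2 to −92, while the others lay at −84.8 to −83.4.

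**Figure D1:**
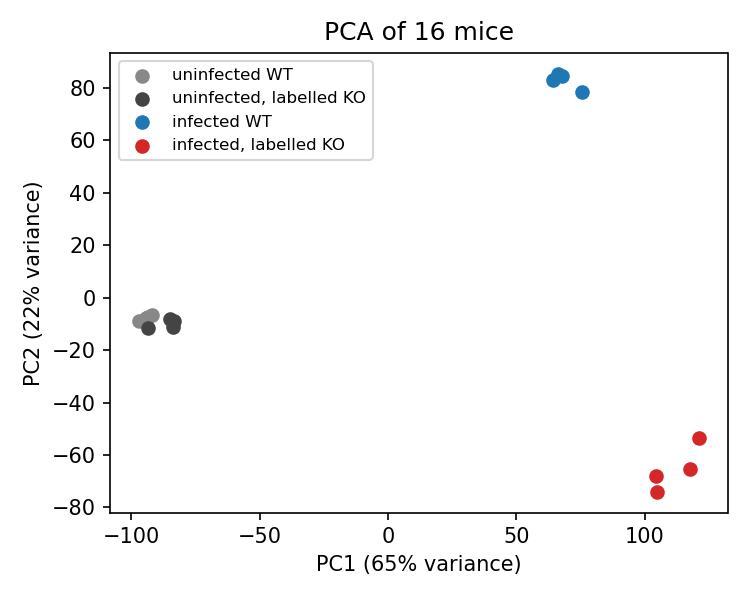
Principal components of log2 CPM over the 16 mice, with 1 point per mouse; the horizontal axis holds 65.1% and the vertical axis 21.9% of the variance. Infected wildtype mice sit at 78.5 to 85.4 on the vertical axis and infected mice labelled knockout at −74 to −53.6.

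Dusp1, the gene targeted in the knockout (entrez 19252, chromosome 17, 26505591 to 26508472), was not lower in the mice labelled knockout. Its level was 119 ± 54.1 CPM in uninfected wildtype and 105 ± 33.0 CPM in uninfected mice labelled knockout (SD, n = 4 each; exact permutation p = 0.771). With infection it fell to 51.2 ± 5.88 CPM in wildtype mice, a log2 fold change of −1.21 ± 0.33 (SE; edgeR adjusted p = 0.0034; exact permutation p = 0.0857). In infected mice labelled knockout it stood at 817 ± 251 CPM. That is 7.78-fold above uninfected mice of that label, a log2 fold change of 2.96 ± 0.34, and 16.0-fold above infected wildtype mice, a log2 fold change of 4 ± 0.36 (exact permutation p = 0.0286 for each, the smallest that 70 assignments allow in a two-sided test). The counts cover the whole gene and which part was deleted is not given in the sources used here. Dusp1 therefore does not check the genotype labels, and every direction between genotypes rests on the labels alone.

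**Figure D2:**
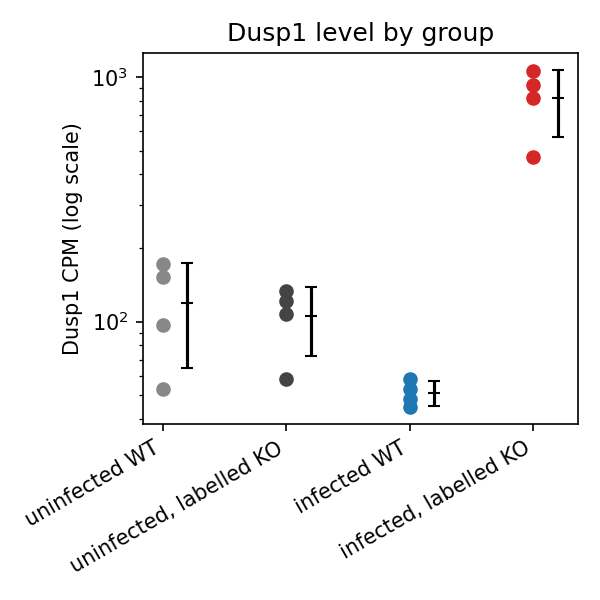
Dusp1 level in CPM on a log axis, with 1 point per mouse in each of the 4 groups and the mean with SD of 4 mice beside the points. The infected mice labelled knockout lie between 471 and 1057 CPM, above the 44.9 to 173 CPM of the other 12 mice.

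Infection of wildtype mice raised innate immune and neutrophil genes in the liver and lowered genes of hepatocyte metabolism. By camera the neutrophil and the amino acid and urea lists passed at the preset correlation alone (adjusted p = 0.11 and 0.146 with an estimated correlation). Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960226), rose from 1.47 ± 0.552 to 740 ± 246 CPM, a log2 fold change of 8.98 ± 0.38. Cps1, the first enzyme of the urea cycle (chromosome 1, 67122426 to 67231267), fell from 6245 ± 1332 to 77.4 ± 7.80 CPM, a log2 fold change of −6.33 ± 0.28. Of 13678 genes tested, 4715 rose and 4819 fell past an adjusted p of 0.05, of which 2319 and 2671 by at least 2-fold. Changes are relative to the TMM scale. With library totals alone the median gene moved by 0.22 on the log2 scale and the split was 5843 up and 3807 down, and without the 50 most abundant genes in those totals it was 5976 and 3752.

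The largest rises in wildtype mice included genes nearly silent without infection. Col22a1, a collagen gene, and Ccdc33 had 0 counts in all 4 uninfected mice and 9.57 ± 1.14 and 9.34 ± 3.27 CPM after infection, at least 294-fold and at least 287-fold higher against a floor of 3 counts over the group. Psors1c2 had 2 counts in the uninfected group and a ratio of 523 (95% counting interval 144 to 4320). Reg3b, an antibacterial lectin, had a ratio of 785 (95% counting interval 268 to 3810, log2 fold change 9.48) and Reg1, of the same family, a log2 fold change of 8.80 ± 2.43. These last values rest largely on infected wildtype mouse 3: without it Reg3b had a log2 fold change of 7.24 and Reg1 of 2.54 with the call lost (adjusted p = 0.23), and without uninfected mouse 1 or 2 they were 10.44 and 9.53. Among genes that met the naming rule, the largest falls were in Cyp8b1, which makes cholic acid (from 318 ± 110 to 0.821 ± 0.208 CPM), Hao2, a peroxisomal oxidase (1 count after infection, 573-fold lower with a 95% counting interval of 102 to 22700), and Aox3, an aldehyde oxidase (from 1394 ± 241 to 3.92 ± 1.10 CPM). They were followed by Hsd3b2 (from 81.3 ± 25.4 to 0.248 ± 0.269 CPM), Keg1 (from 216 ± 52.1 to 0.645 ± 0.153 CPM) and Cyp2b9 (from 89.3 ± 89.2 to 0.265 ± 0.105 CPM). Hao2 had a log2 fold change of −8.51, −6.92 without uninfected mouse 1 and −9.87 without infected mouse 5. Cyp2b9 went from −8.37 to −7.78 without uninfected mouse 1, and Hsd3b2 from −8.39 to −9.37 without infected mouse 3.

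Immune and stress lists rose in infected wildtype mice. All 26 measured genes of NF-kB and Toll-like receptor signalling rose (camera adjusted p = 5.35e-13), among them Irak3, a brake on Toll-like receptor signalling, by 6.74 ± 0.15 on the log2 scale and Icam1, a leukocyte adhesion molecule, by 4.90 ± 0.14. Of 25 acute phase genes 23 rose (adjusted p = 5.94e-12), with Saa1, serum amyloid A, from 32.5 ± 6.71 to 5105 ± 343 CPM and Orm1, orosomucoid, from 225 ± 24.3 to 2868 ± 103 CPM. Of 27 cytokine and chemokine genes 23 rose and 1, Il18, fell by 1.53 on the log2 scale (adjusted p = 3.23e-09), with the neutrophil chemoattractant Cxcl2 up by 6.12 ± 0.20 and the monocyte chemoattractant Ccl2 by 7.30 ± 0.30. These 3 lists held with an estimated correlation (adjusted p = 0.00229, 0.00405 and 0.0253). Interferon-induced genes rose in 30 of 32 cases, Gbp5 and Gbp3 by 6.19 ± 0.24 and 6.06 ± 0.26 (adjusted p = 1.86e-12, and adjusted p = 0.0914 with an estimated correlation). Oxidative stress and metal response genes rose in 13 of 15 (adjusted p = 8.70e-06, and adjusted p = 0.0838 with an estimated correlation). Genes of p53 and cell death rose in 15 of 19 (adjusted p = 4.40e-05, and adjusted p = 0.0681 with an estimated correlation). Kinase-induced genes rose in 22 of 28 (adjusted p = 4.94e-05, and adjusted p = 0.13 with an estimated correlation), as did endoplasmic reticulum stress genes in 14 of 21 (adjusted p = 0.0212, and adjusted p = 0.418 with an estimated correlation).

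Metabolic lists fell in infected wildtype mice, and none of these calls held with an estimated correlation. All 21 amino acid and urea genes fell, with Hal, which degrades histidine, from 518 ± 103 to 10.3 ± 2.46 CPM (adjusted p = 7.37e-10, and adjusted p = 0.146 with an estimated correlation). All 24 oxidative phosphorylation genes fell, Sdhb and Ndufb5 by 1.91 and 1.43 on the log2 scale (adjusted p = 3.23e-09, and adjusted p = 0.228 with an estimated correlation). Of 25 xenobiotic metabolism genes 20 fell, with the cytochrome P450 genes Cyp2e1 from 5655 ± 1059 to 220 ± 27.0 CPM and Cyp1a2 from 652 ± 93.1 to 50.7 ± 8.66 CPM (adjusted p = 9.69e-09, and adjusted p = 0.155 with an estimated correlation). Of 17 bile acid genes 15 fell, the bile salt export pump Abcb11 at −6.18 and the uptake carrier Slco1a1 at −4.82 on the log2 scale (adjusted p = 7.10e-07, and adjusted p = 0.156 with an estimated correlation). Falls also led in the negative acute phase (13 of 15, adjusted p = 2.55e-06, and adjusted p = 0.0951 with an estimated correlation). They led too in growth hormone and IGF1 genes (10 of 12, adjusted p = 0.000673, and adjusted p = 0.0914 with an estimated correlation) and lipogenesis (19 of 23, adjusted p = 0.000673, and adjusted p = 0.276 with an estimated correlation). The same held for coagulation, where 16 fell and 3 rose of 23 (adjusted p = 0.000229, and adjusted p = 0.202 with an estimated correlation). In complement 17 fell and 4 rose of 22 (adjusted p = 0.00167, and adjusted p = 0.241 with an estimated correlation). Glucose metabolism had 14 falls and 2 rises of 22 (adjusted p = 0.00184, and adjusted p = 0.276 with an estimated correlation). Circadian genes had 12 and 5 of 17 (adjusted p = 0.0170, and adjusted p = 0.216 with an estimated correlation), and fatty acid oxidation genes 17 and 6 of 26 (adjusted p = 0.0212, and adjusted p = 0.61 with an estimated correlation). Cholesterol synthesis, with 16 up and 6 down of 25 (adjusted p = 0.19), cell cycle (6 and 3 of 19, adjusted p = 0.402), lipid storage and transport (7 and 13 of 24, adjusted p = 0.464) and glucocorticoid targets (7 and 5 of 14, adjusted p = 0.465) did not pass as lists. Counts adjusted over the list alone were the same except for complement, with 5 up, and cell cycle, with 2 down.

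Marker genes of other cells moved with infection in wildtype mice beside these groups. All 16 neutrophil markers rose, Hdc, which makes histamine, by 4.19 ± 0.15 and Il1r2, a decoy receptor, by 7.86 ± 0.35 on the log2 scale (adjusted p = 8.22e-09, and adjusted p = 0.11 with an estimated correlation). Without uninfected mouse 2 Il1r2 stood at 9.08. Kupffer cell markers fell in 12 of 13, with Clec4f from 55.0 ± 9.15 to 0.620 ± 0.268 CPM and Cd5l from 46.7 ± 7.14 to 0.285 ± 0.0770 CPM (adjusted p = 9.95e-07, and adjusted p = 0.11 with an estimated correlation). Hepatocyte markers fell in 10 of 12, Apoh by 2.17 on the log2 scale (adjusted p = 5.29e-05, and adjusted p = 0.201 with an estimated correlation). Monocyte markers rose in 9 and fell in 2 of 13, with the integrin Itgam up by 5.62 ± 0.18, Thbs1 up by 5.20 ± 0.19 and Cx3cr1 at −2.05 ± 0.46 (adjusted p = 0.000892, and adjusted p = 0.201 with an estimated correlation). Sinusoidal endothelial markers fell in 11 of 16 and rose in 3 (adjusted p = 0.0065, and adjusted p = 0.228 with an estimated correlation). Erythroid markers fell in 3 of 4 (adjusted p = 0.0293, and adjusted p = 0.155 with an estimated correlation). T and NK cells (5 up and 1 down of 9, adjusted p = 0.0628), cholangiocytes (6 up of 8, adjusted p = 0.123), stellate cells (3 up and 5 down of 14, adjusted p = 0.174) and B cells (2 up and 1 down of 7, adjusted p = 0.773) did not pass. Nor did pancreas, with 2 up of 3 and a median log2 fold change of 8.06 (adjusted p = 0.822). The adipose list, with 1 measured gene, was not tested. Rn45s, the ribosomal RNA precursor, ranged over 34570 to 45143 CPM in uninfected and 44983 to 54883 CPM in infected wildtype mice.

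In mice labelled knockout, infection raised immune, cytokine, kinase-induced and cell death genes. By camera, metabolic lists were lower at the preset correlation alone (adjusted p = 0.504 to 0.651 with an estimated correlation). Cxcl2 rose from 0.709 ± 0.0386 to 664 ± 32.8 CPM, a log2 fold change of 9.86 ± 0.23, and Csf3, the granulocyte growth factor, from 0.284 ± 0.176 to 285 ± 140 CPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 291 ± 155 to 1.82 ± 0.834 CPM. Of the genes tested 5190 rose and 5492 fell, 3174 and 3508 of them by at least 2-fold. With library totals alone the median gene moved by −0.42 and the split was 3752 up and 7139 down, and without the 50 most abundant genes in those totals it was 4031 and 6829.

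Among the largest rises in mice labelled knockout, Fgf23, a phosphate-regulating hormone, and Pax6, a developmental transcription factor, had 0 counts in the uninfected group and 19.9 ± 2.91 and 14.2 ± 5.28 CPM after infection, at least 543-fold and at least 405-fold higher. Npy, neuropeptide Y, was at least 149-fold higher, and its log2 fold change of 9.83 was 9.18 without infected mouse 8. Il1f6, an interleukin of the IL-1 family, had a ratio of 1440 (95% counting interval 258 to 57000), and its log2 fold change of 9.89 was 11.50 without uninfected mouse 10, which held its only count. Among genes that met the naming rule, the largest falls after Cyp7a1 were Nrep (log2 fold change −7.24 ± 0.47), Nr0b2, a nuclear receptor that represses bile acid synthesis (−7.05 ± 0.69), Hsd3b2 (−6.92 ± 0.39), Keg1 (−6.64 ± 0.29) and Cyp2u1 (−6.57 ± 0.27).

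Of the lists, 5 held in mice labelled knockout with an estimated correlation. NF-kB and Toll-like receptor genes rose in 25 of 26, with Tnfaip3, a negative regulator of NF-kB, from 6.86 ± 1.34 to 1838 ± 218 CPM and Irak3 up by 7.57 ± 0.16 on the log2 scale (camera adjusted p = 1.23e-11, and adjusted p = 0.00423 with an estimated correlation). Acute phase genes rose in 24 of 25, Steap4 from 196 ± 26.0 to 8793 ± 718 CPM and Saa1 by 7.00 ± 0.19, while Saa4 fell by 1.43 (adjusted p = 1.09e-10, and adjusted p = 0.00655 with an estimated correlation). Cytokine and chemokine genes rose in 23 and fell in 1 of 27, Il33, an alarmin, by 6.59 ± 0.21, with Ccl6 at −1.09 ± 0.28 (adjusted p = 2.55e-08, and adjusted p = 0.0276 with an estimated correlation). Kinase-induced genes rose in 27 of 28, the early response gene Ier3 by 8.21 ± 0.19 and Fosl2, a subunit of AP-1, by 4.02 ± 0.12 (adjusted p = 4.94e-09, and adjusted p = 0.0372 with an estimated correlation). Genes of p53 and cell death rose in 18 of 19, Casp4, an inflammatory caspase, by 4.23 ± 0.18 and Mdm2, the p53 ligase, by 2.42 ± 0.12 (adjusted p = 2.86e-06, and adjusted p = 0.0276 with an estimated correlation). All 32 interferon-induced genes rose, Irf7 by 3.46 ± 0.13 and Gbp5 by 6.09 ± 0.23 (adjusted p = 7.90e-13, and adjusted p = 0.0805 with an estimated correlation). Endoplasmic reticulum stress genes rose in 15 of 21 (adjusted p = 0.00598, and adjusted p = 0.601 with an estimated correlation).

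Cholesterol synthesis genes fell in 22 of 25 in mice labelled knockout, with Sc5d, a sterol desaturase, from 340 ± 28.9 to 51.5 ± 5.86 CPM (adjusted p = 9.94e-06, and adjusted p = 0.504 with an estimated correlation). Bile acid genes fell in 13 of 17, the export pumps Abcc2 and Abcb11 by 4.02 and 4.48 on the log2 scale (adjusted p = 0.000731, and adjusted p = 0.589 with an estimated correlation). Xenobiotic genes fell in 19 of 25 (adjusted p = 0.00273, and adjusted p = 0.644 with an estimated correlation). Amino acid and urea genes fell in 16 of 21 (adjusted p = 0.00598, and adjusted p = 0.651 with an estimated correlation) and lipogenesis genes in 14 of 23 (adjusted p = 0.0160, and adjusted p = 0.651 with an estimated correlation). The other 12 pathway lists had adjusted p from 0.0909 to 0.686. With library totals 2 of these passed, oxidative phosphorylation (adjusted p = 0.00316, with 23 of 24 genes down in place of 10) and glucocorticoid targets (adjusted p = 0.0407). Beside them, 16 of 16 neutrophil markers rose, Il1r2 by 8.00 ± 0.33 and Hdc by 3.92 ± 0.15 (adjusted p = 2.21e-06, and adjusted p = 0.191 with an estimated correlation). All 13 Kupffer cell markers fell, with the iron exporter Slc40a1 from 250 ± 27.9 to 3.36 ± 0.503 CPM and Csf1r down by 3.93 (adjusted p = 2.21e-06, and adjusted p = 0.191 with an estimated correlation). Sinusoidal endothelial markers fell in 14 of 16, the growth factor receptors Kdr and Flt4 at −4.55 ± 0.13 and −2.26 ± 0.08, with Cdh5 at 1.5 ± 0.09 (adjusted p = 0.000387, and adjusted p = 0.191 with an estimated correlation). The other 8 tested marker lists had adjusted p from 0.174 to 0.916, monocyte markers 0.0462 with library totals. Among these, the pancreas list had 2 genes up and a median log2 fold change of 5.36. Rn45s ranged over 32962 to 45762 CPM in uninfected and 45776 to 55685 CPM in infected mice labelled knockout. Malat1, a nuclear RNA chosen after its values were seen, ranged over 7187 to 8304 and 11441 to 13416 CPM in these groups, and 6413 to 7149 CPM in infected wildtype mice. Counts adjusted over the list alone differed for the negative acute phase, 0 up and 5 down in place of 1 and 6, and cell cycle, 7 down in place of 8.

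Without infection, mice labelled knockout differed from wildtype mice in far fewer genes, with higher cell cycle, Kupffer and stellate marker genes. On the first principal component of the 8 uninfected mice, knockout mouse 3 lay at −12, among wildtype mice at −32.2 to −9.9. The other knockout mice lay at 32.3 to 36.5. The labels used here give no ages, so a difference in age cannot be told apart from genotype in this comparison. By camera, the cell cycle and Kupffer lists passed at the preset correlation alone (adjusted p = 0.157 and 0.0633 with an estimated correlation), and the stellate list passed both ways. Ccnd1, a cyclin of the start of the cell cycle, stood at 55.0 ± 25.5 against 16.5 ± 2.12 CPM, and Col3a1, a fibrillar collagen, at 106 ± 56.2 against 26.0 ± 6.51 CPM. Rps2, a ribosomal protein gene (entrez 16898, chromosome 17, 24718121 to 24721927), had the smallest adjusted p (2.16e-14): 2.37 ± 0.142 against 48.2 ± 3.24 CPM, a log2 fold change of −4.34 ± 0.09, with copies elsewhere in the genome that make its counts uncertain. Of 13678 genes 451 were higher and 298 lower, of which 194 and 91 by at least 2-fold. The count ran from 244 without knockout mouse 9 to 1409 without knockout mouse 3, with 305 without wildtype mouse 1, 298 without wildtype mouse 2, 483 without wildtype mouse 9, 370 without knockout mouse 7 and 316 without knockout mouse 10. With library totals that leave out the 50 most abundant genes, 589 were higher and 216 lower.

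Among genes that met the naming rule, the largest other differences in uninfected mice labelled knockout were higher H2-Bl, an antigen-presentation gene (log2 fold change 4.19 ± 0.37), Dnaic1, a dynein chain of cilia (3.62 ± 0.48), Mt1, metallothionein (3.41 ± 0.51) and Asns, asparagine synthetase (2.80 ± 0.41). Acsm2 (2.67 ± 0.49) was higher too, as was Scara5, a ferritin receptor (2.32 ± 0.32). Lower were Mme, the peptidase neprilysin (from 95.7 ± 55.5 to 3.06 ± 1.20 CPM), and the urinary protein genes Mup12 (−4.18 ± 0.62) and Mup20 (−2.96 ± 0.51). So were Col5a3, a collagen gene (−3.21 ± 0.41), and Acot3 (−2.72 ± 0.65, adjusted p = 0.0242). Acsm2 stood at 3.31 without wildtype mouse 6, Mup12 at −5.09 without knockout mouse 9 and Col5a3 at −2.57 without wildtype mouse 1. Acot3 lost its call without wildtype mouse 1 or 2 or knockout mouse 7 or 9 (adjusted p = 0.0811, 0.0697, 0.0756 and 0.0911) and stood at −3.70 without knockout mouse 10.

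Several lists were higher in uninfected mice labelled knockout by camera, of which the stellate markers held with an estimated correlation. Cell cycle genes were higher in 11 of 19, and 15 adjusted over the list alone, with Ccna2, a cyclin of DNA replication, up by 2.1 ± 0.32 (adjusted p = 1.25e-10, and adjusted p = 0.157 with an estimated correlation). Glucocorticoid targets were higher in 7 of 14, 9 adjusted over the list alone, Zbtb16 by 1.73 ± 0.29 and the metallothionein Mt2 by 3.25 ± 0.57 (adjusted p = 3.69e-07, and adjusted p = 0.157 with an estimated correlation). Interferon-induced genes were higher in 5 of 32, and adjusted over the list alone 8 were higher and 1 lower, Ifi44 by 0.90 ± 0.13 and Zbp1 by 1.08 ± 0.19 (adjusted p = 6.84e-07, and adjusted p = 0.4 with an estimated correlation). Acute phase genes were higher in 7 of 25, 10 adjusted over the list alone, Itih3 by 0.55 ± 0.09 and Saa4 by 1.05 ± 0.19 (adjusted p = 0.000167, and adjusted p = 0.157 with an estimated correlation). Growth hormone and IGF1 genes were higher in 3 of 12, with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.00599, and adjusted p = 0.297 with an estimated correlation). Fatty acid oxidation genes were lower in 4 of 26, 5 adjusted over the list alone, Vnn1, a pantetheinase, at −1.85 ± 0.31 and Crat, carnitine acetyltransferase, at −1.13 ± 0.21 (adjusted p = 1.07e-05, and adjusted p = 0.658 with an estimated correlation). Oxidative phosphorylation had 0 of 24 genes past the edgeR threshold and 0 adjusted over the list alone, with a list median of −0.17 (camera adjusted p = 0.00186, and adjusted p = 0.871 with an estimated correlation).

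Kupffer cell markers were higher in 5 of 13, and in 12 adjusted over the list alone, with the scavenger receptor Marco up by 1.89 ± 0.32 and the complement chain C1qc by 0.84 ± 0.15 (adjusted p = 7.88e-08, and adjusted p = 0.0633 with an estimated correlation). Stellate markers were higher in 4 of 14, and in 9 adjusted over the list alone, with Lum, lumican, up by 0.95 ± 0.17 (adjusted p = 9.68e-06, and adjusted p = 0.0224 with an estimated correlation). Complement genes were higher in 3 of 22, 6 adjusted over the list alone, among them Cfp, properdin, at 0.65 and C5ar1, the C5a receptor, at 0.84 (adjusted p = 0.00186, and adjusted p = 0.549 with an estimated correlation). Lipogenesis genes were lower in 2 of 23, malic enzyme Me1 at −1.05 and the desaturase Scd1 at −1.22, with 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.00186, and adjusted p = 0.658 with an estimated correlation). Endothelial markers were higher in 2 of 16, Cdh5 at 0.39 and Flt4 at 0.30, 3 adjusted over the list alone (adjusted p = 0.00255, and adjusted p = 0.307 with an estimated correlation). Monocyte markers were higher in 1 of 13, Ms4a6c at 1.18, 2 adjusted over the list alone (adjusted p = 0.00355, and adjusted p = 0.329 with an estimated correlation). All 7 of these genes from Cfp to Ms4a6c lost their call without knockout mouse 9, with adjusted p of 0.0607 (Cfp), 0.0699 (C5ar1), 0.0956 (Me1), 0.124 (Scd1), 0.0683 (Cdh5), 0.115 (Flt4) and 0.0576 (Ms4a6c). Some also lost it without wildtype mouse 1 (Cfp, 0.0539; Me1, 0.0595; Cdh5, 0.0642; Flt4, 0.0884) or wildtype mouse 2 (C5ar1, 0.0648; Scd1, 0.0752; Flt4, 0.0645). Others lost it without wildtype mouse 9 (C5ar1, 0.0551; Me1, 0.0767; Scd1, 0.122; Flt4, 0.0917) or knockout mouse 7 (Me1, 0.0518; Scd1, 0.118; Cdh5, 0.0596; Flt4, 0.0953). Without knockout mouse 10 it was lost for 4 of them (Me1, 0.0634; Scd1, 0.0629; Cdh5, 0.0553; Flt4, 0.0557). Scd1 also lost it without knockout mouse 3 (0.0504), infected wildtype mouse 3 or 5 (0.0517 and 0.0503) or infected knockout mouse 8 (0.0506). The lipogenesis list lost its call without wildtype mouse 9 (adjusted p = 0.0604) and the monocyte list without wildtype mouse 6 or knockout mouse 9 (0.0605 and 0.147). The other 15 pathway lists had adjusted p from 0.106 to 0.793 and the other 7 tested marker lists from 0.104 to 0.991.

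Genes past the threshold in uninfected mice lay more often near Dusp1 than elsewhere. Within 10 Mb of Dusp1, 32 of 339 genes (9.44%) were past it, against 715 of 13286 others (5.38%), an odds ratio of 1.83 (95% interval 1.22 to 2.67; Fisher's exact p = 0.0024). Of the 32 genes, 23 had the same sign in infected mice and 18 of these were past the threshold there too. In all 331 of the 749 genes were past it in both with the same sign, so much of this overlap is expected anywhere. At an adjusted p under 0.01 the odds ratio was 6.29 (Fisher's exact p = 1.63e-10). Fisher's test takes genes as independent, so its p may be too small where related genes lie side by side. Among the genes past the threshold, H2-T24, H2-Bl and H2-T10 lay at 9.5 to 9.61 Mb, and counts of that family are uncertain. The odds ratio of 1.83 fell to 1.26 (Fisher's exact p = 0.171) without uninfected knockout mouse 3, where 42 genes inside were past the threshold and the number elsewhere rose more. It fell to 1.51 (Fisher's exact p = 0.0406) without uninfected wildtype mouse 6. Without uninfected wildtype mouse 1, 2 or 9 it was 3.59, 4.05 and 2.47. Without uninfected knockout mouse 7, 9 or 10 it was 3.42, 4.10 and 3.40. In infected mice, with 70.8% of genes outside past the threshold, the odds ratio was 1.045 (Fisher's exact p = 0.762).

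**Figure D3:**
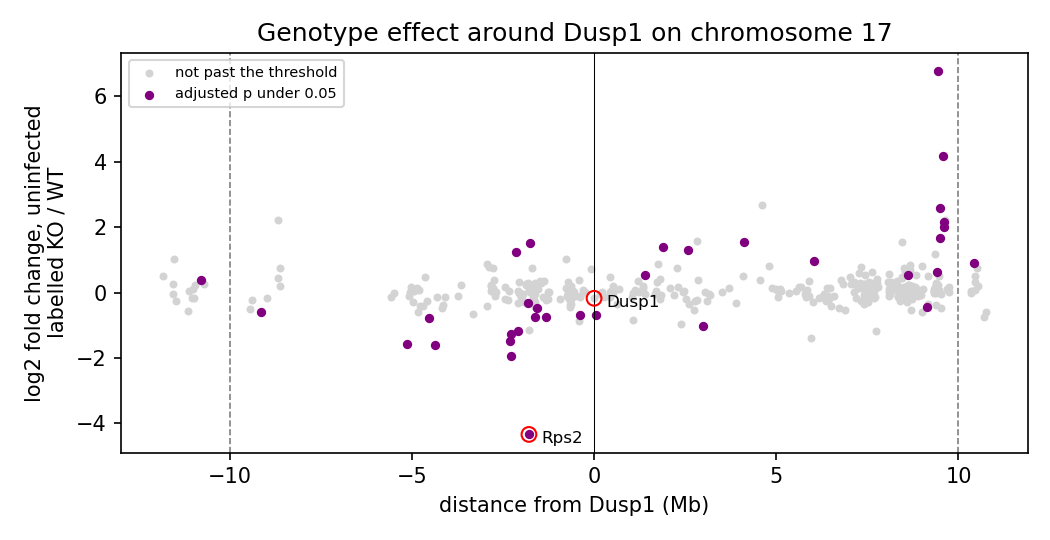
Log2 fold change of uninfected mice labelled knockout against wildtype mice (vertical axis) for genes on chromosome 17 by distance from Dusp1 in Mb (horizontal axis), with 1 point per gene, genes past an adjusted p of 0.05 in purple and dashed lines at 10 Mb. Rps2 lies at −4.34 and Dusp1 at −0.18.

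In infected mice, those labelled knockout had higher hepatocyte, kinase-induced and interferon genes than wildtype mice and lower cholesterol synthesis genes. By camera these lists passed at the preset correlation alone (adjusted p = 0.535, 0.266, 0.288 and 0.266 with an estimated correlation). Mx1, an interferon-induced antiviral gene (chromosome 16, 97447035 to 97462906), stood at 749 ± 282 against 4.31 ± 0.643 CPM, and Cps1 at 3179 ± 1140 against 77.4 ± 7.80 CPM. Lss, lanosterol synthase (chromosome 10, 76531565 to 76557139), stood at 5.58 ± 1.78 against 114 ± 15.1 CPM, a log2 fold change of −4.34 ± 0.23. Of 13678 genes 5123 were higher and 4564 lower, of which 2669 and 2442 by at least 2-fold. The split depends on scaling. With library totals alone the median gene moved by −0.66, 2425 genes were higher and 7699 lower, and 407 genes past the threshold both ways had the opposite sign. Without the 50 most abundant genes in those totals the counts were 2918 and 7024.

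Apart from Mx1, the largest differences among genes that met the naming rule were in genes near silent in the other genotype. Higher in mice labelled knockout were Tub (75.9 ± 30.5 against 0.0372 ± 0.0285 CPM) and Il19, an interleukin of the IL-10 family (log2 fold change 8.51 ± 0.98). Higher too were Olig1, a transcription factor of the glial lineage (7.39 ± 1.03), Pax6 (6.65 ± 0.41) and Abra (6.60 ± 0.74). Il19 stood at 9.69 without wildtype mouse 5 and 7.35 without knockout mouse 7, Abra at 9.98 without wildtype mouse 5, and Olig1 at 6.23 without knockout mouse 8. Lower were Guca2b and Guca2a, the peptides uroguanylin and guanylin, and Grin2b, a glutamate receptor subunit (16.9 ± 3.53 to 0.107 ± 0.0458 CPM). The chemokine Ccl20 (−7.24 ± 0.68), the glutathione transferase Gsta1 and Ajuba (−6.13 ± 0.29) were lower as well. Guca2b stood at 0.234 ± 0.122 against 88.1 ± 32.3 CPM. Gsta1 was lower by a ratio of 175 (95% counting interval 48.4 to 1450) and Guca2a by 148 (50.5 to 720). Ccl20 stood at −8.34 without knockout mouse 6, and Guca2a went from −7.08 to −8.00 without knockout mouse 7.

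No list held with an estimated correlation in this comparison. Cholesterol synthesis genes were lower in 23 of 25, Mvk, mevalonate kinase, at −3.26 ± 0.21, with Ebp at 1.23 ± 0.12 (camera adjusted p = 1.90e-07, and adjusted p = 0.266 with an estimated correlation). Oxidative stress and metal genes were lower in 12 of 15, with 3 higher (adjusted p = 0.00141, and adjusted p = 0.266 with an estimated correlation). Oxidative phosphorylation genes were higher in 23 of 24, Sdhb by 1.46 ± 0.12 and Cox5a by 0.95 ± 0.09 (adjusted p = 1.44e-05, and adjusted p = 0.347 with an estimated correlation). Coagulation genes were higher in 20 of 23, F13b by 3.84 ± 0.20 and prekallikrein, Klkb1, by 4.11 ± 0.22, with thrombomodulin, Thbd, at −0.88 ± 0.20 (adjusted p = 1.44e-05, and adjusted p = 0.266 with an estimated correlation). Kinase-induced genes were higher in 23 of 28, 24 adjusted over the list alone, Spry2, a feedback inhibitor of kinase signalling, by 2.60 ± 0.16 and Jund by 1.91 ± 0.12 (adjusted p = 3.15e-05, and adjusted p = 0.266 with an estimated correlation). Interferon-induced genes were higher in 26 and lower in 2 of 32, 27 and 2 adjusted over the list alone, Ifit3 by 4.27 ± 0.21, with the GTPase Igtp at −1.73 ± 0.15 (adjusted p = 5.42e-05, and adjusted p = 0.288 with an estimated correlation). Amino acid and urea genes were higher in 17 of 21, Hpd by 4.93 ± 0.27, with Gldc at −1.36 ± 0.24 (adjusted p = 0.000161, and adjusted p = 0.324 with an estimated correlation). Xenobiotic genes were higher in 18 of 25, Cyp2e1 by 3.77 ± 0.21 and Cyp1a2 by 2.87 ± 0.16, with the xenobiotic receptor Nr1i2 at −2.46 ± 0.27 (adjusted p = 0.000161, and adjusted p = 0.316 with an estimated correlation). Complement genes were higher in 16 of 22, Masp1 by 2.56 ± 0.11 and C9 by 2.83 ± 0.19, with Cfb at −1.28 ± 0.11 (adjusted p = 0.000781, and adjusted p = 0.266 with an estimated correlation).

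Also higher in infected mice labelled knockout were negative acute phase genes (11 of 15, adjusted p = 0.000781, and adjusted p = 0.266 with an estimated correlation). So were glucose metabolism genes (17 of 22, adjusted p = 0.00133, and adjusted p = 0.288 with an estimated correlation) and circadian genes (13 of 17, adjusted p = 0.00423, and adjusted p = 0.266 with an estimated correlation). Growth hormone and IGF1 genes (10 of 12, adjusted p = 0.00574, and adjusted p = 0.266 with an estimated correlation) and glucocorticoid targets (11 of 14, adjusted p = 0.0062, and adjusted p = 0.266 with an estimated correlation) were higher as well. Cytokines were higher in 18 and lower in 4 of 27 (adjusted p = 0.00679, and adjusted p = 0.266 with an estimated correlation). NF-kB and Toll-like receptor genes were higher in 16 and lower in 5 of 26, 17 and 5 adjusted over the list alone (adjusted p = 0.0118, and adjusted p = 0.266 with an estimated correlation). Their median of 0.58 turned to −0.09 under library totals. Under that scaling oxidative phosphorylation had 7 genes higher and 3 lower (median 0.12), complement 11 and 8 (0.28) and interferon-induced genes 16 and 5 (0.47). Acute phase genes were higher in 13 and lower in 5 of 25, 13 and 6 adjusted over the list alone (adjusted p = 0.0447, and adjusted p = 0.288 with an estimated correlation). Their median of 0.65 turned to −0.03 under library totals, and the call was lost without infected knockout mouse 7 (adjusted p = 0.0597). Hepatocyte markers were higher in 11 of 12, Apoh by 1.91 ± 0.10, with the transcription factor Hnf4a at −1.05 ± 0.15 (adjusted p = 0.000237, and adjusted p = 0.535 with an estimated correlation). The other 7 pathway lists had adjusted p from 0.167 to 0.992 and the other 10 tested marker lists from 0.162 to 0.876. TMM factors were 1.19 to 1.24 in infected wildtype and 0.690 to 0.850 in infected knockout mice. The 50 most abundant genes took 31.6 to 34.1% and 37.4 to 40.6% of counts in these groups, and reads outside genes averaged 42.5 ± 1.48% and 46.2 ± 1.27% (SD, n = 4 each).

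The infection effect itself differed between the genotypes in 8032 of 13678 genes, by the interaction test, with a higher value in mice labelled knockout in 4134 and a lower value in 3898. Among these, 1215 genes rose in both genotypes and more in mice labelled knockout, 405 rose in both and less, 1228 fell in both and more, and 699 fell in both and less. Another 580 rose in wildtype and fell in mice labelled knockout, and 458 did the opposite. Past the threshold in wildtype alone were 1198, in mice labelled knockout alone 2167, and in neither 82. With library totals alone the median moved by −0.64, the split was 1860 higher and 6868 lower, and 46 genes had the opposite sign. Without the 50 most abundant genes in those totals it was 2071 and 6558.

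Gadd45a, a stress-induced gene of growth arrest (chromosome 6, 67035096 to 67037407), had an infection log2 fold change of −0.93 ± 0.33 in wildtype and 7.21 ± 0.40 in mice labelled knockout, a difference of 8.13 ± 0.51 (adjusted p = 5.87e-09). Mme (chromosome 3, 63295211 to 63383713) fell by 5.29 in wildtype and stood at 2.04 ± 0.47 in mice labelled knockout, a difference of 7.32 ± 0.67. Mx1 differed by 7.04 ± 0.41, Tub by 10.69 ± 1.44, Olig1 by 9.05 ± 1.32 and Pax6 by 8.86 ± 2.26. Dusp1 differed by 4.17 ± 0.47 (adjusted p = 1.71e-06). In the other direction, Ajuba rose by 3.00 ± 0.21 in wildtype and was at −3.18 ± 0.32 in mice labelled knockout, and Fgf21, a fasting and stress hormone of the liver, rose by 3.97 ± 0.66 and was at −2.80 ± 0.84. Grin2b differed by −7.63 ± 1.10, Guca2b by −7.37 ± 1.19, Col22a1 by −7.32 ± 2.16 and Tbx1, a developmental transcription factor, by −6.07 ± 0.94. Col22a1 lost its call without uninfected knockout mouse 3 (−5.73, adjusted p = 1). Pax6 lost its call with run 1 alone (adjusted p = 1) and Col22a1 with run 2 alone (adjusted p = 1). Pax6 and Col22a1 had 0 counts in whole groups, so their fitted differences depend on the prior count. Olig1 was at 9.85 without uninfected knockout mouse 3 and 7.87 without infected knockout mouse 8. Grin2b was at −8.45 without uninfected wildtype mouse 9, Fgf21 at −6.07 and −7.98 without uninfected knockout mouse 7 and infected knockout mouse 2, and Tbx1 at −6.66 without infected knockout mouse 7.

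By list, the interaction was lower for cholesterol synthesis in 23 of 25 genes, Lss rising by 1.09 ± 0.20 in wildtype and at −2.95 ± 0.22 in mice labelled knockout (camera adjusted p = 1.88e-07, and adjusted p = 0.318 with an estimated correlation). It was lower for oxidative stress and metal genes in 11 of 15, Srxn1, sulfiredoxin (chromosome 2, 152105524 to 152111376), rising by 5.14 ± 0.17 in wildtype against −0.24 ± 0.15 in mice labelled knockout (adjusted p = 0.000579, and adjusted p = 0.305 with an estimated correlation). It was higher for oxidative phosphorylation in 23 of 24, Sdhb by 1.79 ± 0.17 (adjusted p = 1.48e-06, and adjusted p = 0.364 with an estimated correlation). Amino acid and urea genes were higher in 17 of 21, Cps1 by 5.07 ± 0.33 (adjusted p = 3.05e-05, and adjusted p = 0.364 with an estimated correlation). Coagulation genes were higher in 19 of 23, F13b by 3.89 ± 0.26 (adjusted p = 3.05e-05, and adjusted p = 0.305 with an estimated correlation). Kinase-induced genes were higher in 18 of 28, Jund by 2.01 ± 0.17 (adjusted p = 3.05e-05, and adjusted p = 0.305 with an estimated correlation). Xenobiotic genes were higher in 19 of 25, Cyp2e1 by 3.97 ± 0.27 (adjusted p = 6.35e-05, and adjusted p = 0.364 with an estimated correlation). The negative acute phase was higher in 11 of 15, with Serpina6, the corticosteroid-binding globulin, falling by 4.79 in wildtype and at 0.13 ± 0.17 in mice labelled knockout (adjusted p = 0.000693, and adjusted p = 0.318 with an estimated correlation). Higher too were circadian genes (12 of 17, adjusted p = 0.00116, and adjusted p = 0.305 with an estimated correlation) and glucose metabolism (15 of 22, 16 adjusted over the list alone, adjusted p = 0.00253, and adjusted p = 0.364 with an estimated correlation). Interferon-induced genes (18 of 32, adjusted p = 0.00253, and adjusted p = 0.439 with an estimated correlation) and complement genes (14 of 22, adjusted p = 0.00816, and adjusted p = 0.364 with an estimated correlation) were higher too. The same held for NF-kB and Toll-like receptor genes (14 of 26, adjusted p = 0.0117, and adjusted p = 0.305 with an estimated correlation) and cytokines (13 of 27, adjusted p = 0.0184, and adjusted p = 0.364 with an estimated correlation). Growth hormone and IGF1 genes followed (6 of 12, adjusted p = 0.0403, and adjusted p = 0.364 with an estimated correlation). Under library totals the interaction had 11 interferon-induced genes higher and 11 lower (median 0.1), 10 and 7 NF-kB and Toll-like receptor genes (0.08), 11 and 6 complement genes (0.2) and 8 and 1 oxidative phosphorylation genes (0.27). The growth hormone and IGF1 call was lost without infected knockout mouse 6 (adjusted p = 0.0634) and with GC trends removed (adjusted p = 0.0592). Hepatocyte markers were higher in 11 of 12 (adjusted p = 0.000105, and adjusted p = 0.47 with an estimated correlation). The other 9 pathway and 10 tested marker lists had adjusted p from 0.083 to 0.799 and 0.119 to 0.965.

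Across genes, which are not independent replicates, the infection log2 fold changes of the genotypes correlated with Pearson r = 0.697 and Spearman rho = 0.662. These comparisons share no library. Of 7840 genes past the threshold in both, 6802 (86.8%) had the same direction. Up in both were 3302 genes against 1789 for independent lists, and down in both 3500 against 1935. The genotype effects in uninfected and infected mice correlated across genes with r = 0.1. Of 534 genes past the threshold in both, 331 (62.0%) had the same direction and 203 the opposite. Up in both were 211 genes against 169 for independent lists, and down in both 120 against 99.4.

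**Figure D4:**
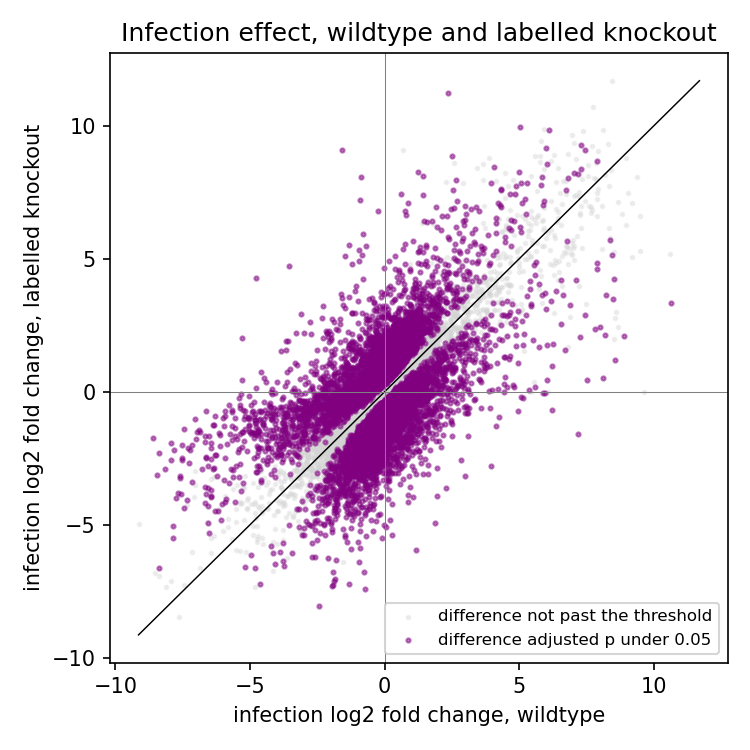
Infection log2 fold change in wildtype mice (horizontal axis) and in mice labelled knockout (vertical axis), with 1 point per gene, the diagonal of equal change, and the 8032 genes whose difference passed the interaction test in purple. The 13678 genes scatter about the diagonal with Pearson r = 0.697.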

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

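The tests of the wrong label of uninfected mouse 3, of exchanged genotype labels, of scaling for Dusp1, and of GC content, scaling and joint variation for cholesterol synthesis genes were chosen after the result was seen. The age list was written after the position of mouse 3 and other genes of the uninfected mice had been seen, and before its own genes were looked at.

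Dusp1 differed between the genotypes in its response to infection by 4.17 on the log2 scale, with its highest levels in infected mice labelled knockout. As for single mice with exchanged genotype labels, 0 of 16 libraries had Rps2 on the other genotype's side. Rps2 was picked out by its difference between the uninfected groups, so for uninfected mice this is not an independent check. Infected mice entered that choice only through the spread shared by all 16 mice, so for them the check is not fully independent either. With that limit, their levels argue against an exchange of single mice among them. These were 45.2 to 54.8 CPM in wildtype mice and 4.42 to 4.80 CPM in mice labelled knockout. Against scaling, the log2 fold change between infected genotypes was 3.32 with library totals. An exchange of both whole labels is not excluded by Rps2, and reads from a remaining part of the targeted gene, whose counts per exon were not used here, may add to the count. The genotype as labelled, in infected mice, stays open as the biological explanation and was not tested apart from these.

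Uninfected knockout mouse 3 lay at −93.6 on the first principal component, apart from the other 3 of its group at −84.8 to −83.4. That component mainly parts infected from uninfected mice. On the first component of the 8 uninfected mice alone, with 42.4% of their variance, mouse 3 lay at −12. There the other 3 lay at 32.3 to 36.5 and wildtype mice at −32.2 to −9.9. As for a wildtype mouse under a wrong label, its Rps2 level was 2.33 CPM. The other uninfected knockout mice had 2.21 to 2.55 and uninfected wildtype mice 44.2 to 51.7 CPM. Rps2 was picked out by its difference between these groups, mouse 3 among them, so its level is not an independent check. Over 42 genes within 10 Mb of Dusp1 the median position of mouse 3 was 0.75 (quartiles 0.28 to 1.06). On this scale 0 is the wildtype mean and 1 the mean of the other knockout mice, and the value alone leaves both sides open. Over 1301 genes on other chromosomes the median position was 0.3 (quartiles 0 to 0.63), nearer the wildtype mean. Both sets of genes were chosen by a difference between wildtype mice and the other knockout mice, which also set 1 on the scale. Such a choice draws the position of a mouse left out of it below 1. A younger age of the other 3 mice may contribute: a list of genes that fall in liver after birth was higher in uninfected mice labelled knockout (camera p = 0.000232; p = 0.0297 with an estimated correlation), with a median of 0.82 and 3 of 11 genes past the threshold, 6 adjusted over the list alone. Of its genes, chosen after their values were seen, H19 stood at 0.111 CPM in mouse 3 and 2.73 to 2.78 in the others, and Igf2bp3 at 0.0554 and 10.5 to 16.5 CPM, while Cdkn1c (2.05 and 1.89 to 2.12) did not set it apart. Of the 11 genes mouse 3 was lowest of its group in 6 and highest in 2. The list was compared between all 4 mice and wildtype, so mouse 3 against the others was not tested, the labels used here give no ages, and no other biological explanation was tested.

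Cholesterol synthesis genes were lower in infected mice labelled knockout, and their infection effects differed by a median of −2.35, Lss by −4.04. Between infected genotypes, GC content is argued against by a list median of −2.24 after its trend was removed, and scaling by list medians of −2.25, −2.93 and −2.24 under 3 other scalings, each with 23 of 25 genes lower. The genes of the list vary together between mice. Fry, a test of a list against no change that keeps their correlation, gave an adjusted p of 2.73e-08 between infected genotypes. That argues against joint variation alone as the reason that these genes differed from no change. Of all genes tested 70.8% were past the threshold in this comparison, so the pass does not set the list apart. That the list differed more than other genes was not shown by camera (adjusted p = 0.266 with an estimated correlation, and 0.318 for the interaction). The combination of genotype and infection may act on these genes, and stays open.

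The infection effects differed between the genotypes by the interaction test in 8032 genes. For single genes the differences on the log2 scale were 10.69 for Tub, 9.05 for Olig1, 8.86 for Pax6, 8.13 for Gadd45a, 7.32 for Mme, 7.04 for Mx1, 5.07 for Cps1, 4.91 for Serpina6, 3.97 for Cyp2e1, 3.89 for F13b, 2.01 for Jund and 1.79 for Sdhb. They were −7.63 for Grin2b, −7.37 for Guca2b, −7.32 for Col22a1, −6.77 for Fgf21, −6.18 for Ajuba, −6.07 for Tbx1 and −5.38 for Srxn1. Col22a1 lost its call without uninfected knockout mouse 3 (−5.73, adjusted p = 1). Olig1 stood at 9.85 and 7.87 without uninfected knockout mouse 3 and infected knockout mouse 8, Grin2b at −8.45 without uninfected wildtype mouse 9, Fgf21 at −6.07 and −7.98 without uninfected knockout mouse 7 and infected knockout mouse 2, and Tbx1 at −6.66 without infected knockout mouse 7.

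List medians of this difference, for lists past the threshold by camera at the preset correlation and none with an estimated correlation, were 2.57 for xenobiotic metabolism, 2.26 for amino acid and urea metabolism, 1.81 for glucose metabolism, 1.64 for cytokines, 1.62 for circadian genes, 1.61 for kinase-induced genes, 1.6 for hepatocyte markers, 1.45 for the negative acute phase, 1.24 for growth hormone and IGF1, 1.1 for coagulation, 0.93 for oxidative phosphorylation, 0.85 for complement, 0.75 for interferon-induced genes, 0.71 for NF-kB and Toll-like receptor genes and −1.16 for oxidative stress and metal genes. The growth hormone list lost its call without infected knockout mouse 6 (adjusted p = 0.0634).

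Single mice stood far from the other 3 of their group in 17 of 164 groups examined by Dixon's ratio. Chance alone gives about 1 in 20 groups for normally distributed values, a rate that need not hold for CPM. It does not hold for genes of a few counts: in 4 of the 17 the other 3 mice had 0, which gives the highest ratio at any level. So 17 was not tested against chance. Infected wildtype mouse 3 had Reg3b at 93.2 CPM (others up to 6.56), Reg1 at 106.7 CPM (others up to 0.727) and Hsd3b2 at 0.647 CPM (others up to 0.161). Infected wildtype mouse 5 had Keg1 at 0.416 CPM (others from 0.704), and Hao2 at 0.0347 and Abra at 0.208 CPM, where the others had 0. Uninfected knockout mouse 3 had H2-Bl at 12.7 CPM (others up to 5.60), Acsm2 at 2.49 CPM (others from 7.45) and Col22a1 at 0.0554 CPM (others 0). Uninfected knockout mouse 10 had Il1f6 at 0.0484 CPM (others 0), mouse 9 had Mx1 at 3.06 CPM (others up to 2.28), and mouse 7 had Grin2b at 0 CPM (others from 0.0942). Infected knockout mouse 8 had Olig1 at 63.8 CPM (others up to 13.4) and mouse 2 had Cyp7a1 at 3.06 CPM (others up to 1.55). Uninfected wildtype mouse 6 had the ribosomal precursor Rn45s at 45140 CPM (others up to 35770) and mouse 2 had Tbx1 at 0.0769 CPM (others up to 0.0466).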

How the results depend on the processing

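The alternatives without the 50 most abundant genes in the totals, with GC trends removed, and leaving out each mouse in the tests of position and relation were chosen after seeing the data. For named genes and lists 7293 values kept their side of the threshold, 135 fell below it and 61 passed it. Directions turned under library totals. Of genes past the threshold, 407 for genotype infected, 46 for the interaction and 15 for infection in mice labelled knockout had the opposite sign. The medians of the acute phase (0.65 to −0.03) and NF-kB lists (0.58 to −0.09) turned for genotype infected. So did that of endoplasmic reticulum stress (0.26 to −0.4). Camera, which compares a list with the other genes, called this last list there (adjusted p = 0.0408) with its direction unchanged. The median over all genes was −0.61 under that scaling. The genotype effect in uninfected mice moved most: from 749 genes (451 higher, 298 lower) to 167 (110, 57) at an adjusted p under 0.01, to 1322 (677, 645) with DESeq2 and to 2791 (1343, 1448) with voom, and 285 were higher with only the 8 mice compared; causes were not tested. With library totals, 2425 genes were higher and 7699 lower in infected mice labelled knockout, and the interaction had 1860 and 6868; without the 50 most abundant genes in those totals they were 2918 and 7024, and 2071 and 6558. The median of the infected genotype effect was then −0.46, against −0.61 with these genes in the totals and −0.61 with GC trends removed too, a removal that centres each bin on the library and so cannot tell; so a few abundant genes do not account for the whole shift.

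With an estimated correlation, pathway lists past the threshold went from 20, 12, 9, 17 and 15 to 3, 5, 0, 0 and 0 for infection in wildtype, infection in mice labelled knockout, genotype uninfected, genotype infected and the interaction, and marker lists from 6, 3, 4, 1 and 1 to 0, 0, 1, 0 and 0. By fry, which tests each list against no change, 9 marker lists passed for infection in mice labelled knockout, 6 for genotype infected and 4 for the interaction, and 5 pathway lists for genotype uninfected. With library totals 2 marker lists passed for genotype infected and 2 for the interaction. Oxidative phosphorylation then passed for infection in mice labelled knockout (adjusted p = 0.00316, 23 of 24 genes down in place of 10), and 8 of its genes in place of 23 were higher for the interaction. Bile acid genes passed for genotype infected (adjusted p = 0.00817) and the interaction (adjusted p = 0.00365), and lipid storage genes for the interaction (adjusted p = 0.0142). The relation of the infection effects had r = 0.708 over genes with a mean of at least 5 CPM; causes were not tested.

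Mouse numbers do not pair the mice: over 8 pairs that share a number across groups the correlations of deviations ran from −0.054 to 0.074. The fit with the number as a block, which uses up most degrees of freedom, called 14 genes (10 higher, 4 lower) for genotype uninfected, 6333 (3246 higher) for genotype infected and 3186 (1612, 1574) for the interaction.

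Leaving out each mouse gave 9134 to 9753 genes for infection in wildtype (4490 to 4901 up, 4427 to 4960 down), 10527 to 10863 in mice labelled knockout (5079 to 5318 up, 5315 to 5582 down), 244 (without knockout mouse 9) to 1409 (without knockout mouse 3) for genotype uninfected (167 to 800 up, 77 to 609 down), 9279 to 9891 for genotype infected (4766 to 5228 up, 4451 to 4740 down) and 7666 to 8120 for the interaction (3777 to 4154 up, 3754 to 4022 down). For genotype uninfected, 305, 298 and 483 genes passed without wildtype mouse 1, 2 or 9 (294, 278 and 434 of them among the 749), and 370 and 316 without knockout mouse 7 or 10 (348 and 305). Dusp1 ranged over −1.42 to −0.98, 2.75 to 3.13, −0.41 to 0.06, 3.84 to 4.18 and 3.93 to 4.38 in the order above. Pathway lists numbered 20 to 21, 12 to 14, 8 to 11, 16 to 17 and 14 to 17, and marker lists 6 to 7, 3 to 3, 3 to 6, 1 to 1 and 1 to 2; r ran from 0.672 to 0.708. The odds ratio near Dusp1 ran from 1.261 (without uninfected knockout mouse 3, exact p = 0.171) to 4.101 (without knockout mouse 9) in uninfected mice. In infected mice it ran from 0.973 to 1.119. In uninfected mice it was 1.512 (exact p = 0.0406) without wildtype mouse 6 and 3.59, 4.049 and 2.474 without wildtype mouse 1, 2 or 9. It was 3.417 and 3.402 there without knockout mouse 7 or 10. At 16443056 to 24989997 counts per mouse, genes of a few counts limit folds to bounds, and 1.5-fold changes were recovered in 31.3% of cases for genotype uninfected in the simulation.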

Other observations

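The tests that leave out each mouse near Dusp1 and that count genes outside the region were chosen after the result was seen. The list of genes that fall after birth was written after other genes of the uninfected mice had been seen and before its own test, and the other tests of this part were planned.

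Genes that fall in liver after birth, which include imprinted genes of fetal growth, were examined in uninfected mice. Of 11 measured genes, 3 were higher in mice labelled knockout: Igf2bp3, a fetal RNA-binding protein (log2 fold change 5.41 ± 1.01, adjusted p = 0.00729), Cdkn1c, an imprinted cell cycle inhibitor (1.09 ± 0.29, adjusted p = 0.0388), and Plagl1, an imprinted zinc finger gene (1.02 ± 0.29, adjusted p = 0.0499). All genes of this paragraph were chosen after their values were seen. Others did not pass, among them H19 at 4.07 ± 1.36 (adjusted p = 0.0925) and Mest at 0.82 ± 0.24 (adjusted p = 0.0598). Afp, alpha-fetoprotein, was at 0.43 ± 0.43 (adjusted p = 0.627), Igf2 at 0.28 ± 0.34 (adjusted p = 0.688) and Scd2 at 0.3 ± 0.19 (adjusted p = 0.393). Meg3 went the other way, at −1.05 ± 0.52 (adjusted p = 0.271). With infection, Afp stood at 10.7 ± 2.35 CPM in wildtype mice and 0.408 ± 0.304 CPM in mice labelled knockout (SD, n = 4).

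Other splits of the mice into groups of the same sizes gave fewer genes than the real ones. For infection in wildtype mice 1 of 35 splits, the real one, reached 9534 genes, and the highest other gave 0. For infection in mice labelled knockout 1 of 35 reached 10682 (highest other 1), for genotype in infected mice 1 of 35 reached 9687 (highest other 13), and for genotype in uninfected mice 1 of 35 reached 749 (highest other 638). Of 100 drawn splits for the interaction 1, the real one, reached 8032, with 7672 for the highest other. The 4 highest others, from 7562 to 7672, keep the genotypes apart among infected mice and mix them among uninfected mice, so a count nearly as high needs only the genotype difference among infected mice. The split with 638 genes sets uninfected knockout mouse 3 with wildtype mice 1, 2 and 9. By the rule set beforehand the share was under 0.05 in each case. For infection in each genotype and for genotype in infected mice, the wide gap to the other splits argues against chance. For the interaction the share cannot decide, since the counts follow the genotype difference among infected mice. For genotype in uninfected mice the split with 638 genes came near the real one, so chance is not excluded there.

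A hypothesis for the genotype differences near Dusp1 is that a stretch of chromosome from the donor strain stays around a gene targeted in a mixed background. The odds ratio within 10 Mb was 1.832 in uninfected mice, which is consistent with it, and 6.288 at an adjusted p under 0.01 (Fisher's exact p = 1.63e-10). Without uninfected knockout mouse 3 the first value was 1.261 (Fisher's exact p = 0.171), with 42 genes in the region in place of 32 and more elsewhere. It was 1.512 (Fisher's exact p = 0.0406) without uninfected wildtype mouse 6. It was 3.59, 4.049 and 2.474 without uninfected wildtype mouse 1, 2 or 9, and 3.417, 4.101 and 3.402 without uninfected knockout mouse 7, 9 or 10. The p of these tests takes genes as independent, which neighbours need not be. In infected mice the ratio of 1.045 argued against it by the rule written beforehand. That reading was dropped after the result was seen, since 70.8% of genes outside the region were past the threshold and the ratio could hardly rise. Beyond 10 Mb lay 715 such genes in uninfected and 9404 in infected mice, so a stretch around Dusp1 that alters its own genes does not account for most differences in either. Strain differences elsewhere in the genome of these mice of mixed background were not tested and cannot be told apart from genotype. Unequal sex of the mice is argued against, since 0 of 16 libraries had more Xist than Ddx3y.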
